A study of Arabidopsis thaliana with 54 samples.

How the data were processed

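RNA of whole Arabidopsis seedlings was sequenced after 5, 30 or 180 min with guvermectin (GV, 10 µM), indole-3-acetic acid (IAA, 1 µM), trans-zeatin (ZT, 1 µM), epibrassinolide (eBL, 1 µM) or gibberellin A3 (GA3, 1 µM), or without a compound (control). Each of the 18 groups held 3 libraries, 54 in all. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

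The authors deposited 1 table with a column per library, whose FPKM values they made with tools and a genome that the submitters' processing notes name as Bowtie2 2.2.3 and the TAIR10 build. Its header names no unit, and the values were identified as FPKM from the values themselves, since each value times the gene length given beside it was a whole multiple of 1 step per library. The whole-read check allowed a tolerance of 0.05 reads and took 100% of values as whole. The counter, its use of strand and any further scaling are not given in the sources used here, so reads of a gene and an overlapping antisense gene cannot be told apart. Reads of near-identical gene copies may be split between them, and values for the SAUR19 to SAUR24 and SAUR62 to SAUR64 clusters, 2S albumins, light-harvesting and RBCS genes are uncertain for that reason.

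Columns were matched to libraries by the compound, time and number in their names. The hormone and control columns were recognised by name, and the single remaining name was taken as GV by elimination, so every GV value rests on that match. No other per-sample columns were present (0 unmatched). Of 24000 lines, 3 were damaged and left out. Of the 23997 rows used, 23498 matched a locus of the TAIR10.1 reference annotation and 8008 carried a gene name in the table. Gene names are those of the table, and locations are those of TAIR10.1.

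The table held only part of each library. The size of 1 read implied totals of 17.8 to 23.8 M reads per library, of which 27.3% to 41.9% lay in the table. The 209 rows with the largest means began at 344 FPKM and the next row had 10.5 FPKM, so genes between these levels were not analysed here. The table covered 18496 of 27444 protein-coding loci. One read in a 1 kb gene was worth 0.0421 to 0.0562 FPKM, so values near that level rest on few reads.

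Genes with a mean of at least 1 FPKM in at least 1 group were tested (10622, of which 9752 were protein-coding, 73 chloroplast and 22 mitochondrial). The planned test assumed counts. Because the values were FPKM, the planned choice for normalized values was used: limma 3.58.1 in R 4.3.3, with trend and robust settings, on log2(FPKM + 1), 1 mean per group and all 54 libraries in the fit (36 residual degrees of freedom). Fold changes are on this scale, which understates changes of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each compound was compared with the control of the same time, GV with ZT at each time, the control between times, and each compound's effect between times by an interaction contrast.

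Lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over 315 tests, and again with an estimated correlation. The lists, with tested members, were auxin response (26), cytokinin response (13), brassinosteroid induced (5), brassinosteroid biosynthesis (2), gibberellin feedback repressed (5), gibberellin induced (4), abscisic acid response (7), jasmonate response (9), salicylate and pathogen defence (9), ethylene response (3), touch and wounding (8), hypoxia (3), xenobiotic and detoxification (6), circadian clock (6), photosynthesis (15), root marker (9), seed storage (6), cell wall expansion (4), cell cycle (9), nitrate response (2) and purine salvage, transport and degradation (2). A heat shock list had 1 measured member, HSP21, and received no list test. For each hormone's own lists the difference between GV and that hormone was tested as well, in 18 tests.

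Named genes had all treated values on 1 side of all control values and at least 5 FPKM in the higher group. They were ranked by log2 change, with 10 each way for GV at each time, 4 each way for each hormone and for GV minus ZT, and 5 each way for the control over time. Not all ranked genes are described. List examples are the members with the smallest adjusted p, apart from an item that is not reported here.

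The steps were tested on simulated data made from the gene means and a common dispersion of the control libraries at 5 min (8914 genes). Changes were put into the GV and ZT groups at 5 min. For GV, 80.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 95.5% of those changed 4-fold were called. Of unchanged genes 11 were called (5.67% of calls), and none in a group without changes (0). A raised list was called and 0 of 20 random lists were. The simulation held no outlying library, no offset between sets of libraries and no change in time, so these rates may not hold for the real data. Likeness of responses was measured by correlation and covariance across genes, which are not independent replicates. These were set beside 1000 simulations in which the unchanged groups and the control they share were all drawn as noise.

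Alternatives planned before the data were examined were quantile normalization, no low-value filter, a pseudocount of 0.1, a log2 change of at least 1, only the compared groups in the fit, the replicate number as a block, fry as the list test, and each library left out in turn. Added after seeing the data were a fit without eBL 30 min replicate 3, voom in limma on reads recovered from FPKM and gene length, and a reference made of the other 2 compounds for ZT, eBL and GA3 at 30 and 180 min.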

Results

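The study set guvermectin (GV), a purine nucleoside of microbial origin, beside 4 plant hormones in Arabidopsis seedlings. It holds 54 RNA-seq libraries in 18 groups of 3: control, GV (10 µM), the auxin IAA (1 µM), the cytokinin ZT (1 µM), the brassinosteroid eBL (1 µM) and the gibberellin GA3 (1 µM), each at 5, 30 and 180 min. The doses of GV and the hormones differ, so sizes of response are not at matched doses. Implied library totals were 17.8 to 23.8 M reads, with 5.65 to 7.51 M of them in the genes of the table. Replicates of a group correlated at 0.971 or above, except that eBL 30 min replicate 3 stood apart from its group. Pairs with that library differed by 24.2 to 25.3 times the counting error (chi-square over degrees of freedom), against 1.92 to 4.24 for all other pairs.

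At 5 min several of the genes ranked highest by their rise with GV were heat shock genes. HSP21 (AT4G27670, chromosome 4, 13818825 to 13819971, minus strand), a small heat shock protein of chloroplasts, rose by 4.29 ± 0.15 (SE) on the log2 scale, from 0.351 ± 0.253 to 25.4 ± 4.17 FPKM (SD, n = 3; limma adjusted p = 9.08e-25). HSP17.4A and HSP26.5, also small heat shock proteins, rose by 3.89 and 3.65, HSP70-8 by 2.32, and APX2, an ascorbate peroxidase, by 2.98. HSP21 is the only member of the fixed heat shock list that was measured, and the other 4 genes follow from their rank, not from a tested list. All 9 jasmonate genes rose (9 adjusted over the list alone), among them LOX2 by 1.58 and OPR3 by 0.65, which encode enzymes of jasmonate synthesis (camera in limma, adjusted p = 5.93e-08).

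Of 7 abscisic acid genes 4 rose with GV at 5 min (6 adjusted over the list alone, adjusted p = 9.99e-05), with RD29A at 0.88 and KIN1 at 1.29. Touch and wounding genes rose in 4 of 8 cases (4 up and 1 down adjusted over the list alone, adjusted p = 0.0135), with the calmodulin-like CML37 at 1.05. Seed storage genes were lower, with 2 of 6 called (3 adjusted over the list alone, adjusted p = 0.000425). Cruciferin CRC, a storage globulin, fell by 2.07, from 13.4 ± 0.485 to 2.42 ± 0.173 FPKM, and the 2S albumin AT2S2 fell by 1.07. The mean of CRC lay below that of the control with each of the other 4 compounds as well, from 0.867 FPKM with IAA to 4.28 FPKM with eBL. A control group that stood apart thus cannot be told from an effect of GV on CRC. The albumin SESA5 fell by 1.49 and the late embryogenesis gene M17 by 1.38. Root markers were slightly lower (1 of 9 called, 3 adjusted over the list alone, adjusted p = 0.0275), with TIP2-3 at -0.64. Without GV 5 min replicate 3 or Control 5 min replicate 3 the list's adjusted p was 0.0682 or 0.053, and 0.0586 without eBL 30 min replicate 3. In all, 831 genes rose and 336 fell of 10622 tested (limma), and quantile normalization gave 687 and 511. NAD5B, a mitochondrial gene, was listed at 0 in all 3 control libraries and at 7.05, 9.75 and 25.7 FPKM with GV.

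**Figure D1:**
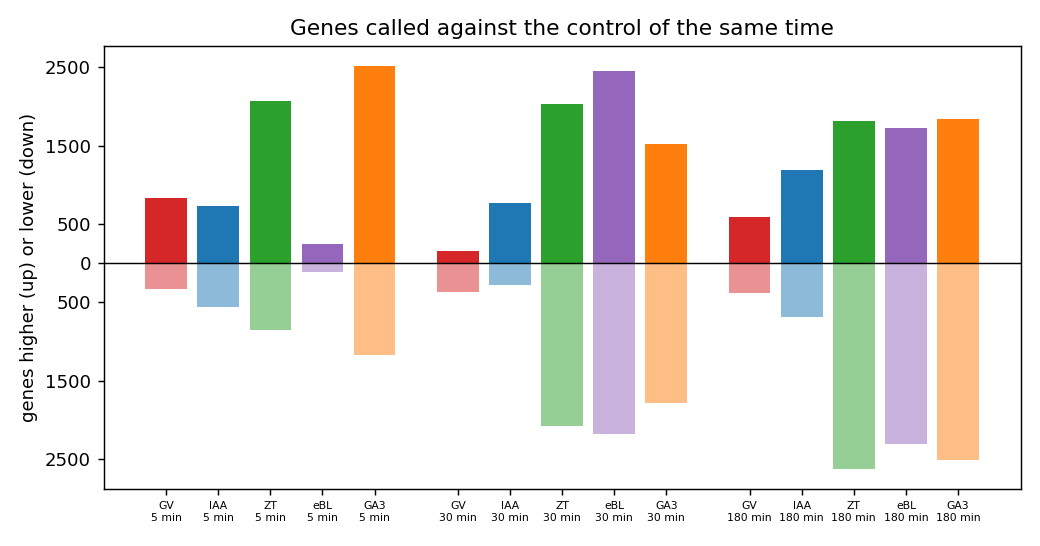
Genes called higher (bars up, full colour) or lower (bars down, pale) than the control of the same time, on the y axis, for the 5 compounds at 3 times on the x axis, 3 libraries per group. GV at 30 min has 160 higher and 370 lower genes, and GA3 at 5 min has 2514 higher and 1170 lower.

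At 30 min with GV the heat shock gene HSP21 lay below the control, having fallen by 2.14 (0.933 ± 0.268 against 7.47 ± 0.415 FPKM, n = 3; limma adjusted p = 2.65e-14). Isocitrate lyase ICL (AT3G21720, chromosome 3, 7652487 to 7656053, minus strand), an enzyme of the glyoxylate cycle that uses stored lipid, fell by 2.07, from 3262 ± 123 to 777 ± 16.9 FPKM. Chalcone synthase CHS fell by 2.30. The control itself moved here: ICL rose by 2.98 and HSP21 by 2.66 in control seedlings between 5 and 30 min. Of the 370 genes lower with GV, 225 were higher in the control at 30 than at 5 min, where independent lists would share 63.9. Both comparisons use the control at 30 min, with opposite signs. Noise in those libraries alone would make the lists overlap, so 63.9 is not the overlap to be had without a change.

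Seed storage genes were higher with GV at 30 min, opposite to 5 and 180 min. Of 6, 3 rose (3 adjusted over the list alone, camera adjusted p = 1.05e-09): CRC by 1.65, AT2S2 by 2.49, and AT2S1, which was listed at 0 in all controls and at a mean of 4.1 FPKM with GV. SESA5 rose by 2.32. At 5, 30 and 180 min CRC was at 13.4, 2.52 and 16.9 FPKM in the control and at 2.42, 10.0 and 3.24 with GV, so both groups moved. At 30 min its mean was also above the control with ZT (12.5) and eBL (4.39), and below it with IAA (0.883) and GA3 (0.59). The morning clock genes LHY and CCA1 fell by 1.29 and 0.89, and 3 of 6 clock genes fell (3 adjusted over the list alone, adjusted p = 0.00058). Cytokinin response genes were lower (3 of 13 called, 6 adjusted over the list alone, adjusted p = 0.00271), with ARR16 at -0.62 and CRF2 at -0.47. In the control ARR16 was at 1.76, 3.71 and 2.51 FPKM at 5, 30 and 180 min. At 30 min it was at 2.07 with GV, 2.025 with IAA, 1.85 with eBL and 1.85 with GA3, and at 11.7 with ZT. A lower ARR16 at 30 min was thus not particular to GV, and each of these comparisons shares the control at 30 min.

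Of the gibberellin feedback genes, GA3OX2, a gibberellin synthesis enzyme, fell by 0.85 with GV at 30 min (1 of 5 called, 2 adjusted over the list alone, adjusted p = 0.00393). Among 6 detoxification genes 3 fell (3 adjusted over the list alone, adjusted p = 0.00954), with CYP81D8 at -0.64. Without GV 30 min replicate 2 the adjusted p was 0.0503. The nitrate reductase gene NIA2 rose by 0.60 (1 of 2 nitrate genes, 1 adjusted over the list alone, adjusted p = 0.00262). Photosynthesis genes were higher with 1 of 15 called (1 adjusted over the list alone, adjusted p = 0.00111), and adjusted p = 0.169 with an estimated correlation. Hypoxia genes were lower with 1 of 3 called (2 adjusted over the list alone, adjusted p = 0.0474), and adjusted p = 0.182 with an estimated correlation. Without GV 30 min replicate 1 or 3 or Control 30 min replicate 2 it was 0.0513, 0.11 and 0.104. Counts were 160 higher and 370 lower genes, and 243 and 347 with quantile normalization. The total of 530 became 823 without eBL 30 min replicate 3 and 317 with only the compared groups in the fit.

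At 180 min GV raised PR1 (AT2G14610, chromosome 2, 6241640 to 6242541, minus strand), a marker of salicylate defence, by 2.29 ± 0.18 (SE), from 1.28 ± 0.0682 to 10.2 ± 0.442 FPKM (SD, n = 3; limma adjusted p = 6.37e-13). PR1 had also risen at 30 min, by 1.11. At 180 min the mean of PR1 lay above the control with every other compound as well, from 2.16 FPKM with ZT to 3.83 FPKM with GA3. In the control PR1 was at 4.23, 2.76 and 1.28 FPKM at 5, 30 and 180 min, so part of the difference at 180 min came with a lower control. Of 9 defence genes 2 rose (3 adjusted over the list alone, camera adjusted p = 0.0263), and adjusted p = 0.0844 with an estimated correlation or 0.0545 without GV 180 min replicate 3. The lectin-like JAL36 rose by 1.73, the vacuolar processing enzyme dVPE by 1.73, the ribonuclease RNS1 by 1.60 and the cutinase CDEF1 by 1.44. Cell wall genes rose in 3 of 4 cases (4 adjusted over the list alone, adjusted p = 0.000183): ATXTH17 by 0.83, XTH4 by 0.43 and XTH24 by 0.44, which encode xyloglucan-modifying enzymes.

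Seed storage genes fell again with GV at 180 min (3 of 6, with 3 down and 1 up adjusted over the list alone, camera adjusted p = 0.000625), with CRC at -2.08 and the oleosins OLEO2 and OLEO1 at -1.62 and -1.15. The mean of CRC at 180 min lay below that of the control with every other compound as well, from 0.167 FPKM with ZT to 13.8 FPKM with IAA. A lower CRC was thus not particular to GV, and each of these comparisons shares the control at 180 min. The seed proteins ECP63 and LEA, of the late embryogenesis class, fell by 2.12 and 2.08. Clock genes were lower with 3 of 6 called (3 adjusted over the list alone, adjusted p = 0.0144, and adjusted p = 0.129 with an estimated correlation or 0.0745 without Control 180 min replicate 1), among them RVE8 at -0.59. For photosynthesis genes, with 1 of 15 called (1 adjusted over the list alone), the adjusted p was 0.0318, and adjusted p = 0.393 with an estimated correlation. It was 0.0738 or 0.0647 without Control or GV 180 min replicate 1. In total 594 genes rose and 380 fell (limma), and 578 and 458 with quantile normalization.

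**Figure D2:**
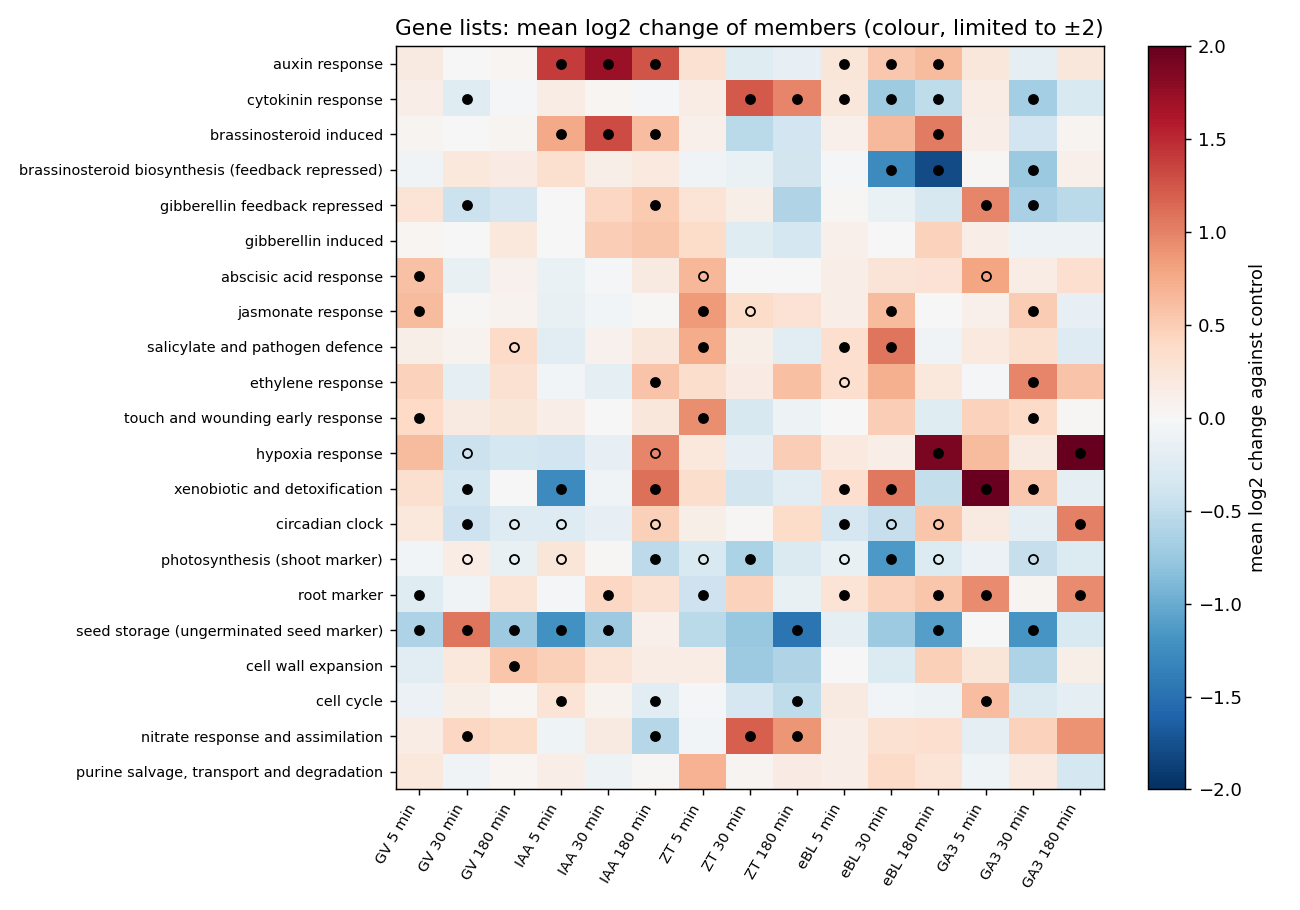
Mean log2 change against the control of the same time (colour, limited to ±2) of the tested members of 21 gene lists (y axis) in 15 comparisons (x axis), 3 libraries per group. Dots mark a camera adjusted p under 0.05, filled where it also held with an estimated correlation and open where it did not; auxin response is at 1.40, 1.73 and 1.26 with IAA and has no dot with GV.

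IAA raised auxin response genes at every time. At 5 min 14 of 26 rose (17 adjusted over the list alone, camera adjusted p = 5.78e-26), led by small auxin-up genes: SAUR62 by 3.69, SAUR19 by 3.38 and SAUR64 by 3.44. At 30 min 24 rose (24 up and 1 down adjusted over the list alone, adjusted p = 3.02e-57), with the auxin repressor gene IAA5 at 3.74, the transcription factor LBD18 at 2.82 and the auxin-conjugating GH3.1 at 2.79. At 180 min 23 rose (25 adjusted over the list alone, adjusted p = 4.45e-26), with LBD18 at 3.44. Brassinosteroid induced genes rose too, in 2, 4 and 3 of 5 cases (2, 5 and 3 adjusted over the list alone, adjusted p = 0.00685, 4.52e-09 and 0.0143). SAUR15, at 2.54 at 5 min, belongs to both lists.

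Detoxification genes fell with IAA at 5 min (5 of 6, 5 adjusted over the list alone, adjusted p = 7.5e-13), with the glucosyltransferase UGT74E2 at -2.85, and 5 rose at 180 min (6 adjusted over the list alone, adjusted p = 6.28e-09), with UGT74E2 at 1.45. Seed storage genes were lower than in the control at 5 and 30 min, in 3 of 6 cases each (4 and 3 adjusted over the list alone, adjusted p = 1.44e-07 and 1.05e-05), with CRC at -2.97 and -0.90. At 5 min CRC lay below the control with all 5 compounds, so a control group that stood apart cannot be told from an effect of IAA on CRC. At 180 min photosynthesis genes fell in 9 of 15 cases (11 adjusted over the list alone, adjusted p = 1.53e-11), with RBCS-2B at -1.33. The number of genes higher and lower was 729 and 562 at 5 min, 761 and 283 at 30 min, and 1192 and 688 at 180 min (limma), and with quantile normalization 687 and 729, 652 and 421, and 934 and 998.

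ZT at 5 min left its own list without a call: cytokinin response genes had a mean log2 change of 0.14 (3 of 13 rose, 3 adjusted over the list alone, camera adjusted p = 0.83). Among the genes with the largest changes, named by rank and not from a tested list, the small heat shock genes HSP17.4A and HSP21 rose by 3.88 and 3.64, the peroxidase PER4 by 3.68 and the transcription factor MYB15 by 3.42. Of 9 jasmonate genes 8 rose (9 adjusted over the list alone, adjusted p = 1e-06), with JAZ10, a jasmonate repressor, at 1.11, and 7 of 8 touch and wounding genes rose (7 adjusted over the list alone, adjusted p = 9.19e-05), with WRKY53 at 1.95. Salicylate defence genes rose in 4 of 9 cases (5 adjusted over the list alone, adjusted p = 0.00271), with AIG1 at 2.15. The abscisic acid list, with 4 of 7 higher (5 adjusted over the list alone, adjusted p = 0.0123), had adjusted p = 0.0977 with an estimated correlation. Root markers fell in 4 of 9 cases (4 adjusted over the list alone, adjusted p = 0.00755), with TIP2-3, a water channel, at -0.99 and PRP3 at -0.93. Photosynthesis genes were lower, with 7 down and 1 up of 15 (8 and 1 adjusted over the list alone, adjusted p = 0.000301) and LHCA1 at -0.56, and adjusted p = 0.131 with an estimated correlation.

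At 30 min with ZT 11 of 13 cytokinin genes rose (11 up and 1 down adjusted over the list alone, camera adjusted p = 2.56e-10). ARR15 (AT1G74890, chromosome 1, 28131447 to 28133025, minus strand), a response regulator of cytokinin signalling, rose by 3.43, the receptor AHK4 by 1.86 and the cytokinin-degrading CKX4 by 1.58. At 180 min 10 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 2.29e-07), with ARR16 at 2.62 and AHK4 at 1.68. Both nitrate genes rose at both times (2 and 2 adjusted over the list alone, adjusted p = 0.00514 and 0.0239), with HRS1 at 1.88 and 1.40. Photosynthesis genes fell at 30 min in 12 of 15 cases (12 adjusted over the list alone, adjusted p = 3.56e-07), with LHCA1 at -0.89. Cell cycle genes fell at 180 min in 7 of 9 cases (8 adjusted over the list alone, camera adjusted p = 0.0128), with CYCD3-1 at -0.71, and seed storage genes in 5 of 6 (5 adjusted over the list alone, camera adjusted p = 0.00159), with CRC at -3.94. At 180 min the mean of CRC lay below the control with every compound and was lowest with ZT (0.167 FPKM).

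ZT changed 2067 genes up and 852 down at 5 min, 2028 and 2075 at 30 min, and 1812 and 2622 at 180 min (limma). Quantile normalization gave 1448 and 1668, 2150 and 1916, and 2281 and 2135. At 30 and 180 min the ZT, eBL and GA3 libraries lay apart from the control, GV and IAA libraries, so each of these 3 compounds was also compared with the mean of the other 2. For ZT that gave 3357 and 4074 genes, against 4103 and 4434 with the control as reference. Such a comparison also calls genes changed by the other compounds alone. Its counts therefore cannot show how much of a compound's own effect remains without the offset.

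eBL at 5 min called few genes, 241 higher and 114 lower (limma), and its own lists were not called (brassinosteroid induced, adjusted p = 0.918, biosynthesis, adjusted p = 0.671). The total of 355 was 183 to 230 when any 1 of the 3 control or 3 eBL libraries was left out and 654 without eBL 30 min replicate 3, and quantile normalization gave 206 higher and 160 lower. The clock genes CCA1 and LNK1 fell by 0.53 and 0.40 (3 of 6 clock genes, 4 adjusted over the list alone, camera adjusted p = 7.5e-06).

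By 30 min eBL lowered both measured genes of brassinosteroid synthesis (2 adjusted over the list alone, camera adjusted p = 0.0037). CYP90B1 (AT3G50660, chromosome 3, 18813949 to 18817405, minus strand), also known as DWF4 and the enzyme of an early step of brassinosteroid synthesis, fell by 1.95, from 12.1 ± 0.888 to 2.38 ± 0.269 FPKM, and CYP85A1 fell by 0.60. At 180 min CYP90B1 fell by 2.61, to 0.562 ± 0.00706 FPKM, and CYP85A1 by 0.96 (adjusted p = 0.00035). Brassinosteroid induced genes rose at 180 min in 3 of 5 cases (4 adjusted over the list alone, adjusted p = 0.00117): the brassinosteroid-inactivating CYP734A1 by 2.15, AGP4 by 1.09 and SAUR15 by 1.41. Auxin response genes were higher at both times, with 14 higher and 3 lower of 26 at 30 min and 14 higher and 1 lower at 180 min (14 and 3, then 15 and 1, adjusted over the list alone, adjusted p = 0.00665 and 1.97e-06). SAUR9 rose by 2.64 at 180 min.

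Cytokinin response genes fell with eBL at 30 min (9 of 13, 10 adjusted over the list alone, adjusted p = 5.78e-05), with CRF5 at -1.85. Defence genes rose at that time in 8 of 9 cases (9 adjusted over the list alone, adjusted p = 7.5e-06), with SIRK at 1.99, and photosynthesis genes fell in 13 and rose in 1 of 15 (13 and 1 adjusted over the list alone, adjusted p = 1.91e-11), with LHCA1 at -1.23. CYP71A12, a P450 of indole defence compounds, rose by 4.40. All 3 hypoxia genes rose at 180 min (3 adjusted over the list alone, adjusted p = 4.98e-05), with sucrose synthase SUS1 at 2.16. The counts were 2450 higher and 2186 lower genes at 30 min, and 1721 and 2315 at 180 min (limma), and with quantile normalization 2258 and 2269, then 2042 and 2040. At 30 min 4005 genes were called without eBL 30 min replicate 3, of which 3209 were among the 4636, and 913 with only the compared groups in the fit. Against ZT and GA3, eBL gave 4450 genes at 30 min, or 2963 without that library, and 2367 at 180 min.

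With GA3 at 5 min all 6 detoxification genes were higher than in the control (6 adjusted over the list alone, camera adjusted p = 1.13e-07). The glutathione transferase GSTU25 was higher by 4.39, at 22.8 against 0.136 FPKM, and UGT73B4 by 2.52. On the first principal component at 5 min the GA3 libraries lay at -34.4 to -34.5 and the control libraries at 17.7 to 17.95. Handling particular to the GA3 libraries was not tested and cannot be told from an effect of GA3. HSP21 rose by 4.40 and HSP17.4A by 4.23. Gibberellin feedback genes, which gibberellin is known to lower, rose in 3 of 5 cases (3 adjusted over the list alone, adjusted p = 0.0225), with the synthesis enzymes GA3OX2 at 2.45 and GA3OX1 at 1.56. Root markers were higher, with 7 up and 1 down of 9 (7 and 1 adjusted over the list alone, adjusted p = 0.00157), and 8 of 9 cell cycle genes rose (8 adjusted over the list alone, adjusted p = 0.00527), with PRP3 at 2.21 and PCNA at 1.04.

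At 30 min gibberellin feedback genes fell with GA3 (4 of 5, 4 adjusted over the list alone, camera adjusted p = 0.0077), with GA3OX2 at -0.71. All 3 ethylene genes rose (3 adjusted over the list alone, adjusted p = 0.00065), while cytokinin genes fell in 8 of 13 cases (8 adjusted over the list alone, adjusted p = 7.5e-06), with CRF2 at -1.80. Seed storage genes fell in 4 of 6 (4 adjusted over the list alone, adjusted p = 0.000129), with AT2S3 at -2.45. Photosynthesis genes were lower in 11 of 15 (13 adjusted over the list alone, adjusted p = 3.83e-05), with LHCA1 at -0.60, and adjusted p = 0.0939 with an estimated correlation. That list was thus lower at 30 min with ZT, eBL and GA3, whose libraries lay apart from the control, and an offset between the sets cannot be told from an effect of each compound. At 180 min all 3 hypoxia genes rose (3 adjusted over the list alone, adjusted p = 6.89e-07), SUS1 by 3.81, ERF071 by 3.38 and HRE1 by 2.26, and the low-oxygen marker AT5G10040 rose by 5.79. Clock genes rose in 5 of 6 cases (5 adjusted over the list alone, adjusted p = 1.57e-05), with CCA1 at 1.93, and all 9 root markers rose (9 adjusted over the list alone, adjusted p = 1.33e-05).

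The gibberellin induced list (4 genes) was not called with GA3 at 5, 30 or 180 min (camera adjusted p = 0.985, 0.878 and 0.94), nor was the purine list (2 genes) with GV (adjusted p = 0.504, 0.806 and 0.827). GA3 gave 2514 higher and 1170 lower genes at 5 min, 1525 and 1784 at 30 min, and 1842 and 2511 at 180 min (limma), and quantile normalization gave 1785 and 2101, 1908 and 1579, and 2144 and 2159. Compared with the mean of ZT and eBL, GA3 gave 2035 genes at 30 min, or 2009 without eBL 30 min replicate 3, and 2973 at 180 min.

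**Figure D3:**
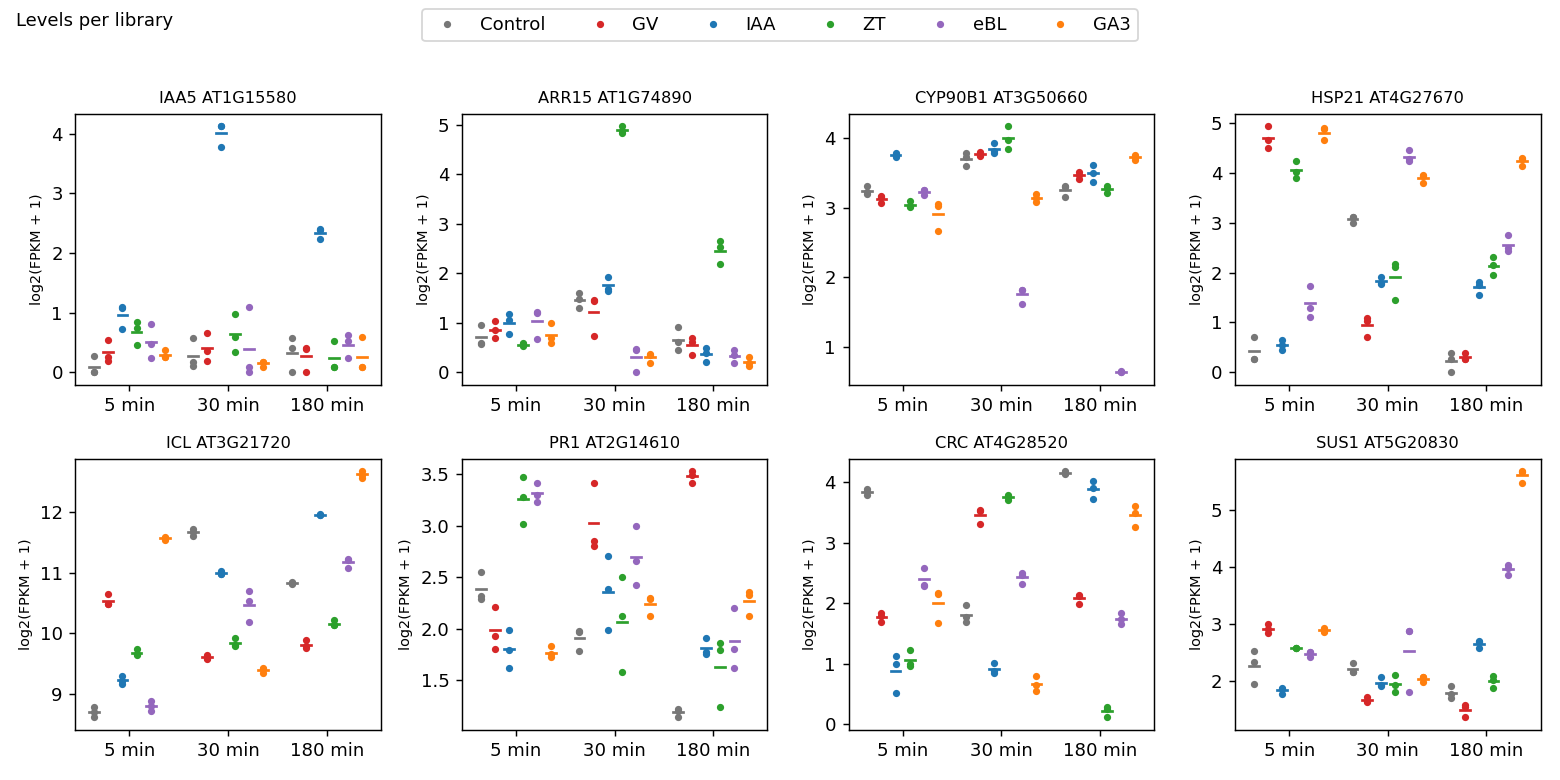
Levels of 8 genes per library, as log2(FPKM + 1) on the y axis, by time on the x axis and compound (colour), with 3 points per group and a line at the group mean. IAA5 is high with IAA at 30 and 180 min, ARR15 with ZT, CYP90B1 is low with eBL at 30 and 180 min, and SUS1 reaches a mean of 47.7 FPKM with GA3 at 180 min.

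GV was then set directly against each hormone's own list. Cytokinin response genes did not differ between GV and ZT at 5 min (mean difference -0.002; camera adjusted p = 0.629), where AHK4, at 0.32 (95% interval 0.12 to 0.51), was the 1 gene called. At 30 and 180 min they were lower with GV (mean differences -1.47 and -1.01; adjusted p = 4.3e-14 and 3.19e-09), in 11 and 10 of 13 genes, with ARR15 at -3.69 and ARR16 at -2.53. Auxin response genes were lower with GV than with IAA by means of -1.22, -1.74 and -1.22 at 5, 30 and 180 min (adjusted p = 2.44e-18, 4.54e-46 and 3.13e-20). Brassinosteroid synthesis genes were higher with GV than with eBL at 30 and 180 min (1.48 and 1.94; adjusted p = 0.000276 and 1.5e-05), and induced genes were lower at 180 min (-0.99; adjusted p = 0.000143). Gibberellin feedback genes were lower with GV than with GA3 at 5 min (-0.70; adjusted p = 0.0269). The remaining tests were not called (adjusted p = 0.152 to 0.915).

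Between GV and ZT, 469 genes were higher with GV and 1151 lower at 5 min, 1859 and 2188 at 30 min, and 2765 and 1846 at 180 min (limma). Quantile normalization gave 845 and 884, 1929 and 2026, and 2231 and 2477. At 30 and 180 min this comparison, like those of GV with eBL and GA3, runs across the sets of libraries that lay apart, and an offset between the sets cannot be told from a difference between compounds. At 5 min the transcription factor MYB15 was lower with GV by a log2 difference of -2.50 and the iron reductase FRO6 was higher by 1.40. At 180 min ACD6, a defence gene, was higher with GV by 2.77.

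The GV and ZT responses at 5 min correlated across genes at 0.695 (Spearman 0.639). Their covariance was 0.109 against 0.0133 in simulations of unchanged groups and a shared control, all drawn as noise. The responses to GV and ZT shared 672 higher genes, where independent lists would share 162, and 224 lower genes, where 27 would. With GA3 the correlation at 5 min was 0.490 and the covariance 0.0858, with eBL 0.409 and 0.0318, and with IAA 0.201 and 0.0225, all 3 against simulated covariances of 0.0132 to 0.0136. At 30 min GV correlated with GA3 at 0.355, IAA at 0.335, ZT at 0.279 and eBL at 0.184. The covariances were 0.0426, 0.0303, 0.0389 and 0.0288 in that order, against simulated values of 0.0154, 0.015, 0.0163 and 0.0338. The simulations used the mean spread of the 3 groups compared, which for eBL included replicate 3, and the spread of the controls alone gave 0.0156 (computed after the data were seen). At 180 min the values were 0.389 with eBL, 0.281 with GA3, 0.263 with ZT and 0.147 with IAA. Their covariances were 0.0579, 0.0452, 0.0429 and 0.0167, against simulated values of 0.0132, 0.0144, 0.014 and 0.0128. Simulated correlations were 0.499 to 0.502, so only covariances can be read against chance, and with 3 controls, which cannot be split into groups of 2, part of the excess may come from the shared controls.

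Control seedlings also changed with time. Between 5 and 30 min 1834 genes rose and 1497 fell, and between 30 and 180 min 1420 rose and 965 fell (limma). Quantile normalization gave 1585 higher and 1870 lower, then 1366 and 1174. ICL rose by 2.98 and HSP21 by 2.66 in the earlier interval, and the beta-glucosidase BGLU19 fell by 2.58. In the later interval CRC rose by 2.35, while HSP21 fell by 2.86. The clock genes CCA1 and LHY fell by 1.93 and 1.64 between 30 and 180 min, and of the touch genes ZAT10 rose by 0.43 and then fell by 0.83.

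**Figure D4:**
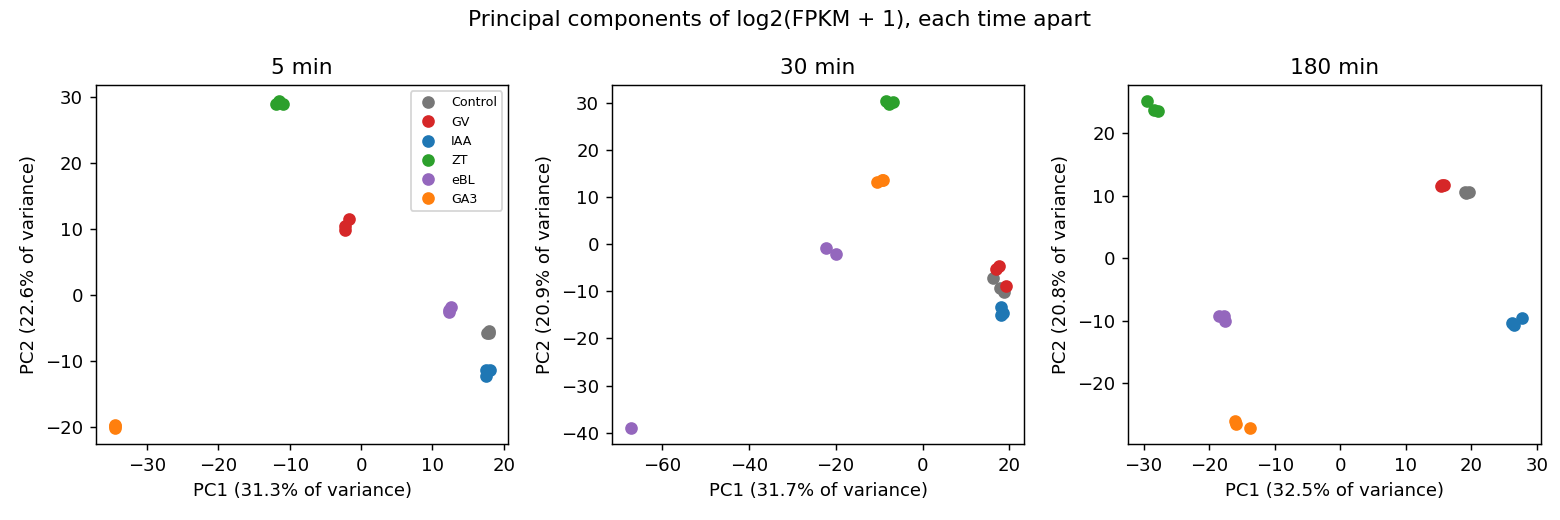
Principal components of log2(FPKM + 1) over the tested genes, computed for each time apart, with PC1 on the x axis and PC2 on the y axis and their percent of variance, 1 point per library and 6 groups of 3 in colour. At 180 min PC1 (32.5% of variance) has ZT, eBL and GA3 on one side and control, GV and IAA on the other, and at 30 min 1 eBL library lies far from the other points.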

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

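Each compound's effect against the control was compared between times by an interaction contrast in limma, and a result is given here where genes passed that test. For GV the effect differed between 30 and 5 min in 1118 genes and between 180 and 30 min in 505. The counts were 916 and 984 for IAA, 4294 and 2026 for ZT, 2879 and 3129 for eBL, and 4191 and 2525 for GA3. Both effects use a control that itself changed in time, so a change in the control enters all 5 compounds. With quantile normalization the split of higher and lower genes moved from 313 and 805 to 517 and 619 for GV (30 minus 5 min), from 361 and 144 to 325 and 214 for GV (180 minus 30 min), from 1646 and 2648 to 2340 and 1919 for ZT (30 minus 5 min), from 1202 and 1927 to 1443 and 1498 for eBL (180 minus 30 min), and from 1453 and 2738 to 2333 and 1966 for GA3 (30 minus 5 min). The median over all genes shifted by -0.13 for ZT and -0.144 for GA3 in that interval. Without eBL 30 min replicate 3 the GV count of 505 was 891 and the IAA count of 916 was 1442. With only the compared groups in the fit the eBL counts were 940 and 1093.

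All tests of explanations in this part were chosen after the result was seen, except the gene length test, the test of a change common to the treated groups at 5 min, and the splits of the libraries.

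At 30 and 180 min the GA3, eBL and ZT libraries lay apart from the control, GV and IAA libraries. A difference in depth is argued against by a ratio of median totals of 1.02, and, for 180 min, a shift in gene length bias by a first axis that kept 0.934 of its variance after a length trend was removed. Length bias at 30 min was not tested. The mean difference between these sets of libraries correlated across genes at 0.52 between 30 and 180 min, and at 0.0846 and -0.145 between 5 min and each of those times. In the authors' column order the GA3, eBL and ZT libraries of 30 and 180 min stand together, before the control, GV and IAA libraries of those times. All libraries of 5 min form a single run, and how the libraries were handled is not given. A technical offset of libraries handled together could give such a value, and so could responses shared by the 3 hormones. The 2 cannot be told apart because each compound lies wholly in 1 set. Biological differences between compounds stay open.

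Replicate 3 of eBL at 30 min stood apart. A lower depth is argued against by a total of 0.978 times that of the other 2 replicates, and a library of any of the other 17 groups by a correlation 0.0259 higher with its own group than with the next (0.874 and 0.848; 95% interval over 200 draws of genes, 0.0228 to 0.0289). The noise of the library lowers both values, and a sample from outside these groups was not excluded. Genes with 1 to 5 reads made up 1.98% of its detected genes against 15.3% to 19.2% elsewhere, and the most frequent read count was 14 against 1. Its variance to mean ratio at 20 to 100 reads was 46.8 against 2.81 to 7.96 in others, and 2.59 times higher, at 121, for genes with more reads. Few starting molecules amplified into many reads may account for this. The rise with level cannot decide it, since in the other libraries that rise ran from 0.828 (ZT 30 min replicate 2) to 8.69 (GV 30 min replicate 3). That explanation stays open, and no biological explanation was tested.

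The responses to GV and ZT at 5 min were alike. The spread between replicate libraries of the shared controls is argued against as the whole cause by a covariance 8.14 times the simulated one. That simulation could not contain a control group that differed as a whole. A change common to all treated groups is argued against as the whole cause by a partial correlation of 0.575 given the other 3 compounds. On PC1 at 5 min the GV, ZT and GA3 libraries lay on the negative side, apart from the control, IAA and eBL libraries. A common cytokinin response could not be decided, since the lower mean change of the cytokinin list was 0.139 and the list passed its test in neither. It remains a hypothesis that the 2 compounds share an early response, and handling that was common to these libraries was not tested.

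For comparisons of 3 against 3 libraries only 10 splits exist, so a share under 0.05 cannot be reached, and these counts, from fits of the compared groups only, are given as values. In each, 1 of 10 splits, the real one, gave as many genes. The real count and the highest of the other splits were, for GV, 1230 and 0, 317 and 1, and 1200 and 0 at 5, 30 and 180 min. For IAA they were 1383 and 0, 855 and 1, and 2354 and 1, and for ZT 3402 and 0, 3786 and 1, and 4546 and 0. For eBL they were 456 and 0, 913 and 0, and 4476 and 0, and for GA3 4199 and 0, 3215 and 0, and 4271 and 0. GV against ZT gave 1800 and 1, 3603 and 0, and 4565 and 0, and the control over time 3260 and 0, and 2445 and 0.

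For the interaction counts 100 splits were drawn, and in all 10 results 1 to 3 of 100, the real one included, gave as many genes. Most of these splits mix treated and control libraries within a time and so break the compound's effect there. They therefore cannot decide whether the effect was equal at both times, nor exclude chance differences between cultures. For 30 minus 5 min the real and highest other counts were 1109 and 599 for GV, 1129 and 304 for IAA, 4557 and 3253 for ZT, 940 and 991 for eBL (3 of 100 as large), and 4686 and 1623 for GA3. For 180 minus 30 min they were 525 and 211 for GV, 1277 and 2400 for IAA (2 of 100), 2092 and 5534 for ZT (2 of 100), 1093 and 3672 for eBL (2 of 100), and 2664 and 1754 for GA3. The larger counts for IAA, ZT and eBL at 180 minus 30 min came from the split that exchanges treated and control libraries at 1 time, which adds the effects in place of subtracting them, and the highest of the rest there were 801, 1574 and 825.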

How the results depend on the processing

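The tests without eBL 30 min replicate 3, with voom and with other compounds as reference were chosen after seeing the data, and the rest were planned. Requiring a log2 change of at least 1 lowered every count by construction: for 5, 30 and 180 min to 177, 82 and 94 (GV), 120, 164 and 241 (IAA), 540, 576 and 700 (ZT), 24, 788 and 507 (eBL), 687, 370 and 576 (GA3) and 197, 577 and 743 (GV against ZT), for the control to 366 and 134, and for the change of effect to 373 and 121 (GV), 200 and 229 (IAA), 1505 and 435 (ZT), 743 and 765 (eBL) and 1477 and 676 (GA3). Without eBL 30 min replicate 3 counts were 654 (eBL 5 min), 823 (GV 30 min), 891 (GV effect, 180 minus 30 min) and 1442 (IAA effect, 30 minus 5 min). Every count whose comparison did not hold eBL at 30 min rose without that library, such as from 1167 to 1608 (GV 5 min) and from 2919 to 3575 (ZT 5 min). All comparisons share an estimate of the spread into which that library entered. Log2 changes of comparisons that do not hold eBL at 30 min are unaltered without that library. Only the estimate of the spread can thus have moved their counts. With only the compared groups in the fit, counts fell to 317 (GV 30 min), 913 (eBL 30 min), and 940 and 1093 (change of the eBL effect). With the other 2 compounds as reference the counts were 2035 for GA3 at 30 min, or 2009 without that library, 2963 for eBL at 30 min without it, and 2367 for eBL at 180 min; the cause was not tested. Leaving out single libraries of the groups compared moved eBL at 5 min to 183 to 230, with fewer samples, and no other count by over 1.5 times. Quantile normalization, no filter, the pseudocount of 0.1 and voom kept all 30 totals, of higher and lower genes together, within 1.5 times. The split by direction moved more with quantile normalization. For ZT at 5 min it went from 2067 higher and 852 lower genes to 1448 and 1668, and for GA3 at 5 min from 2514 and 1170 to 1785 and 2101. Likeness of GV and ZT at 5 min was 0.743 over called genes.

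Of 315 list tests 95 were called, 76 with an estimated correlation and 216 with fry, which does not compare a list with other genes. With fry, GV differed from eBL in brassinosteroid induced genes at 30 min (3.88e-09) and from GA3 in gibberellin feedback genes at 30 and 180 min (0.00185 and 0.00144) and induced genes at 180 min (0.000106). Against the control, fry also called auxin (2.64e-05), cytokinin (0.00796) and gibberellin feedback genes (0.000406) for GV at 5 min, brassinosteroid synthesis genes at 30 and 180 min (0.0177 and 0.0162), and gibberellin feedback (0.000158) and induced genes (0.00438) at 180 min. Lists without a call changed sign with fry (adjusted p): brassinosteroid induced (0.969) and gibberellin induced (0.616) for GV at 5 min, and auxin for GV at 30 min (0.714). With single libraries left out, sign changes occurred, all without a call, for brassinosteroid induced genes with GV at 5, 30 and 180 min (ranges 0.657 to 0.986, 0.621 to 0.974 and 0.68 to 0.989), gibberellin induced genes with GV at 5 min (0.775 to 0.989) and GV minus GA3 at 5 min (0.704 to 0.962); the cause was not tested.

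The replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.0911 to 0.187, with 0 of 45 pairs of groups above 0.1 throughout, and the same number was the best match in 46 of 135. With the replicate block all counts stayed within 1.5 times, such as 1139 for GV at 5 min and 2578 and 1708 for the control over time, and 99 list tests were called. Of the genes named by rule none reversed. NAD5B lost its call under several settings with IAA at 30 min and in the control between 30 and 180 min, but not with GV at 5 min, and the other genes that lost a call are not described above. The count tests planned for a table of counts (DESeq2 and RLE factors) were not run, since the values are FPKM. Depth limits genes near 1 FPKM.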

Other observations

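Isocitrate lyase ICL, a glyoxylate cycle enzyme that supports growth on seed lipid, differed widely between groups at each time. At 5 min it was at 413 ± 23.8 FPKM in the control, 1490 ± 101 with GV and 3038 ± 49.0 with GA3 (SD, n = 3). At 30 min the order differed, with the control at 3262 ± 123 and all 5 compounds below it, from 673 ± 19.6 with GA3 to 2037 ± 39.6 with IAA. At 180 min GA3 was highest, at 6301 ± 237, and GV lowest, at 896 ± 44.6, with the control at 1819 ± 18.4. The genes lower with all 5 compounds at 30 min numbered 30, and each of these comparisons uses the control at 30 min.

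The clock list was tested against the control of the same time only. Its calls at 180 min had camera adjusted p = 0.0905 for IAA and 0.0849 for eBL with an estimated correlation, while the call for GA3 held (0.0114). With GV the list was lower at 180 min, and that call was also lost with an estimated correlation. CCA1, a morning clock gene, was at 9.0 FPKM in the control at 30 min and 1.64 at 180 min, and at 8.97 with GA3, 4.61 with eBL and 4.61 with IAA at 180 min. The storage globulin CRC was at 13.4, 2.52 and 16.9 FPKM in the control at 5, 30 and 180 min, and at 2.42, 10.0 and 3.24 with GV. With IAA it was at 0.867, 0.883 and 13.8, with ZT at 1.1, 12.5 and 0.167, with eBL at 4.28, 4.39 and 2.36, and with GA3 at 3.04, 0.59 and 10.0. At 5 and at 180 min the control was thus the highest of the 6 groups.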
